A study of Mus musculus with 2 samples.

How the data were processed

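MIN6 cells were profiled by RNA-seq, with 1 library labelled normal and 1 labelled high glucose and palmitate. Per the labels' protocols, RNA was extracted with Trizol, and 1 µg per sample went into a stranded mRNA library kit made for Illumina sequencing. The deposited values are RPKM, reads scaled by gene length and by the library's total reads, in 1 table with a column per library and each feature's exon coordinates, strand and length. Per the submitters' processing notes, Trimmomatic 0.36 and edgeR 3.12.1 were used and the genome build was GRCm39. The aligner, the counting tool, the annotation and whether counting used strand are not given in the sources used here. Libraries were assigned by their column names, which match the sample titles, NGP for the library labelled normal and HGP for the library labelled high glucose and palmitate. The labels do not spell out these letters, so whether the libraries differ in palmitate as well as glucose rests on the treatment label alone.

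Multiplying each RPKM by its feature's length and by a common factor gave whole reads for 100% of the values within a tolerance of 0.01 read, the largest deviation being 3.55e-05. The recovered totals were 44149406 reads in the normal and 43727919 in the treated library. Reads served for counting error, for simulation, for shares of reads and for the read counts given for some features. The ratio of treated to normal RPKM was given an exact 95% interval from the Clopper-Pearson interval of the treated share of reads. Reads without molecular identifiers are not independent molecules, so intervals cover counting error only. Many features with few reads had even counts, such as Sox9 with 0 and 2 and Tek with 4 and 12. Some had odd counts, such as mt-Atp6 with 1 and 7. Even counts would arise if both mates of read pairs were counted, and whether they were is not given. In that case the intervals are too narrow and counting error is understated. A feature of mean RPKM 1 or more had a median of 1950 reads over both libraries.

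The comparison used log2 of RPKM plus a pseudocount of 0.5, treated over normal, among features with a mean RPKM of at least 1. This scale understates differences of low features, while ratios printed for single genes are plain RPKM ratios. Features were counted as higher or lower at 2-fold. No p-value was computed, since 1 library per group leaves no replicate error. For comparison with counting error, reads were drawn again 100 times from the mean level of the 2 libraries. The 31 gene lists, the thresholds and most alternatives were fixed before the data were examined. A list with at least 4 measured members was scored by the percentile of its median among 10000 random lists matched in 20 bins of mean expression, and members at least 1.5-fold higher or lower were counted. The 95% interval of a list's median came from 1000 redraws of the reads.

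Genes were named by a rule also fixed then. It took Ldha and the beta cell list, and the 12 highest and 12 lowest ratios among genes with an assigned symbol and a mean RPKM of at least 5. It also took up to 4 members of every other list by size of ratio and the 5 features with the highest RPKM in each library. Further list members are named to show the range within a list, and other genes named outside the rule are stated to be so. Some genes that the rule takes are not reported here. Lists contain some symbols that the table spells otherwise, and these were not replaced.

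The steps were tested on simulated reads for 13207 features of at least 300 bases, drawn at the levels of these libraries. Shorter features were left out of this test. All 50 features set to a log2 ratio of 2 and all 50 set to -2 were found past 2-fold in the right direction. The intervals covered the true ratio for 95.43% of 13007 unchanged features. Of 100 lists of 20 unchanged features 5% fell in the outer tails, and 100% of lists shifted by 0.3 on the log2 scale were found. Smaller list shifts, such as the median of -0.12 of the beta cell list, were not simulated. The simulated features varied independently and list members were picked at random. The 5% therefore does not apply to lists whose genes vary together between cultures.

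Alternatives were pseudocounts of 0.1 and 1, a rescaling of both libraries to the same total, median-of-ratios scaling, and the same total without the 10 most abundant genes. A mean RPKM of at least 5, no filter, a 1.5-fold threshold, intervals that exclude a ratio of 1 and features with an assigned symbol were also tried. Leaving out features under 300 bases, and leaving out those with exons overlapping a gene on the opposite strand (4904 of 13947), were added after seeing the data. GC content per gene symbol and sequence identity were taken from GENCODE annotation of the older build GRCm38, and all coordinates printed are those of the deposited table. In addition to the 31 lists, 3 lists of genes outside them were written for closing tests, with S phase, G2 and M phase, and hypoxia-inducible factor targets. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.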

Results

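RNA was sequenced from MIN6, a mouse insulinoma line that secretes insulin and serves as a beta cell model. There were 2 libraries, 1 from cells labelled normal and 1 from cells labelled high glucose and palmitate, the latter in medium with 33.3 mmol/l glucose, 0.4 mmol/l palmitate and 0.5% bovine serum albumin. The treatment text is the same on both sample records, so the medium of the normal library, and whether it held palmitate, is not stated separately. The normal library held 44149406 reads assigned to genes and the treated library 43727919, both recovered from the RPKM values. Of 30868 listed features, 25337 had reads in the normal library and 25679 in the treated one, and 13947 reached a mean RPKM of 1. With 1 library per group, no difference given here has a replicate check. Intervals in brackets are exact 95% intervals of the ratio of treated to normal, cover counting error only, and compare these libraries, not the conditions. They treat reads as independent, and would be too narrow if both mates of read pairs were counted. A percentile places a gene list's median log2 ratio among 10000 random lists of the same size matched on mean expression, as a description of these libraries. Exon overlaps with other genes are pointed out for some named genes only. Others named without it have them too, among them Ucp2, Bid, Cdkn1a, Cox5a, Cox6c and Sv2b on the opposite strand.

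The series concerns the role of lactate dehydrogenase A in histone lactylation and in how beta cells work when glucose is toxic. Ldha, which encodes the enzyme that converts pyruvate to lactate, was lower in the treated library, at 23.3 RPKM against 30.8 in the normal library, a ratio of 0.759 (0.725 to 0.794). Its log2 ratio of -0.39 stood at the 1.8th percentile of genes of similar expression. Both insulin genes were lower too. Ins1 stood at 34.8 against 66.0 RPKM, a ratio of 0.527 (0.496 to 0.560), and Ins2 at 725.4 against 1197 RPKM, a ratio of 0.606 (0.599 to 0.614). Together the insulin genes took 0.0989% of the reads in the treated library and 0.164% in the normal one. Ldha lies on chromosome 7 at 46490899 to 46505051 on the plus strand, Ins2 on chromosome 7 at 142232393 to 142297118 on the minus strand, and Ins1 on chromosome 19 at 52252735 to 52253914 on the plus strand (GRCm39). None of the 3 shares exons with another listed gene.

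Genes of beta cell identity and function were lower as a group. Of 34 measured members 26 had a log2 ratio below 0 and 8 above it, and the median of -0.12 lay at the 0.03 percentile of random lists. The only members lower by at least 1.5-fold were Ins1 and Ins2, and none was higher by that much. Mafa, a transcription factor of mature beta cells, had a ratio of 0.712 (0.665 to 0.761), and Pdx1, which controls pancreas development and insulin transcription, one of 0.771 (0.750 to 0.793). The glucose transporter gene Slc2a2 stood at 0.773, the glucose-6-phosphatase gene G6pc2 at 0.726, the fatty acid receptor gene Ffar1 at 0.713 and Pax6 at 0.776. The counting interval lay below 1 for 22 of the 34 members and above 1 for 3. Members below 1 also included the channel gene Trpm5 at 0.685 (0.578 to 0.810), Ucn3 at 0.765 (0.635 to 0.920), Ero1b with 61.5 RPKM against 76.9 in the normal library, the prohormone convertase gene Pcsk2 at 0.806 and the incretin receptor gene Glp1r at 0.849. Exons of Trpm5, Pcsk2 and Nkx2-2 overlap genes on the opposite strand, and those of Neurod1 overlap a gene on the same strand. Some members were closer to 1. The transcription factor genes Nkx2-2, Isl1 and Neurod1 had ratios of 0.986, 0.984 and 0.983, and Iapp, the gene of islet amyloid polypeptide, had one of 1.01. The granule protein gene Chgb went the other way, from 5472 to 7345 RPKM, a ratio of 1.34. Genes normally repressed in beta cells, Ldha among them, did not stand apart as a group, with a median of -0.0045 at the 43.11 percentile and 6 of 12 members on either side of 0.

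**Figure D1:**
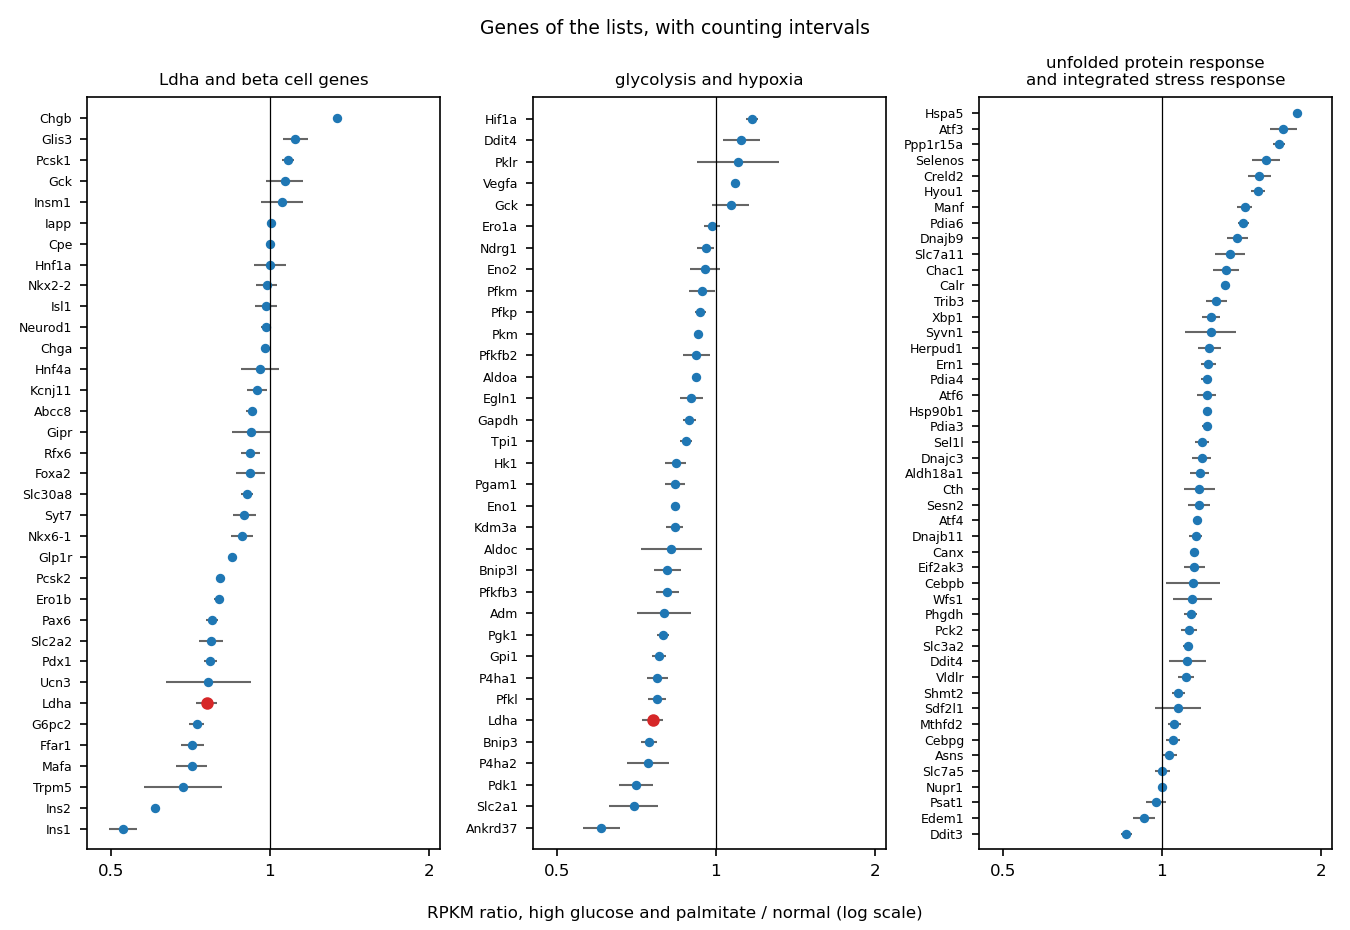
Each point is the ratio of RPKM in the treated library to that in the normal library for 1 gene, on a log axis, and each line its exact 95% counting interval. Left, Ldha (red) and beta cell genes; middle, glycolysis and hypoxia genes; right, genes of the unfolded protein and integrated stress responses. Ldha stands at 0.759 and Ins1 at 0.527, while Hspa5 stands at 1.80.

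Markers of dedifferentiation and of progenitors had a median of 0.28, above nearly all random lists (100.00 percentile), with 7 of 11 members above 0. Of 16 listed members, the rest were below a mean RPKM of 1 and were not scored. Normal and treated reads were 16 and 6 for Aldh1a3, 8 and 12 for Vim, and 0 and 2 for Sox9. Bach2 had 206 and 230, and Gast had none. Mycl, a Myc family gene, was highest at a ratio of 2.01 (1.63 to 2.47), from 0.797 to 1.60 RPKM. It was the only member past 1.5-fold. Myc stood at 1.48 (1.15 to 1.91), from 0.900 to 1.33 RPKM, and the Notch target Hes1 at 1.28 (1.15 to 1.43). Foxo1 at 0.857, Nes at 0.915 and Cck at 0.923 lay below 1. With no filter on low values the list's percentile was 96.04, inside the range that held 95% of random lists. Markers of other islet endocrine cells had a median of 0.19 at the 99.41 percentile over 7 members that went both ways. Gc, found in alpha cells, had a ratio of 1.54 and the somatostatin gene Sst one of 1.30 (1.09 to 1.55), whereas the glucagon gene Gcg had one of 0.641 (0.554 to 0.741).

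Across all 13947 features the libraries were close, with a median log2 ratio of 0.0028 and a range from -0.36 to 0.35 between the 5th and 95th percentiles. At least 2-fold differences were found for 75 features that were higher and 51 that were lower in the treated library. These counts depend on the settings, and a pseudocount of 0.1 gave 105 and 82. Features under 300 bases made up 50 of the former and 40 of the latter, although only 740 of the 13947 were that short, and the counting interval included a ratio of 1 for 21 of the 75 and 22 of the 51. Drawing reads again from equal levels gave a mean of 36.5 such features, at most 52 in 100 draws, against 126 observed. Among features of at least 300 bases it gave a mean of 0.24 and at most 2, against 36 observed. Of these 36, 25 were higher and 11 lower. The drawing treats reads as independent, so it understates counting error if both mates of read pairs were counted.

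**Figure D2:**
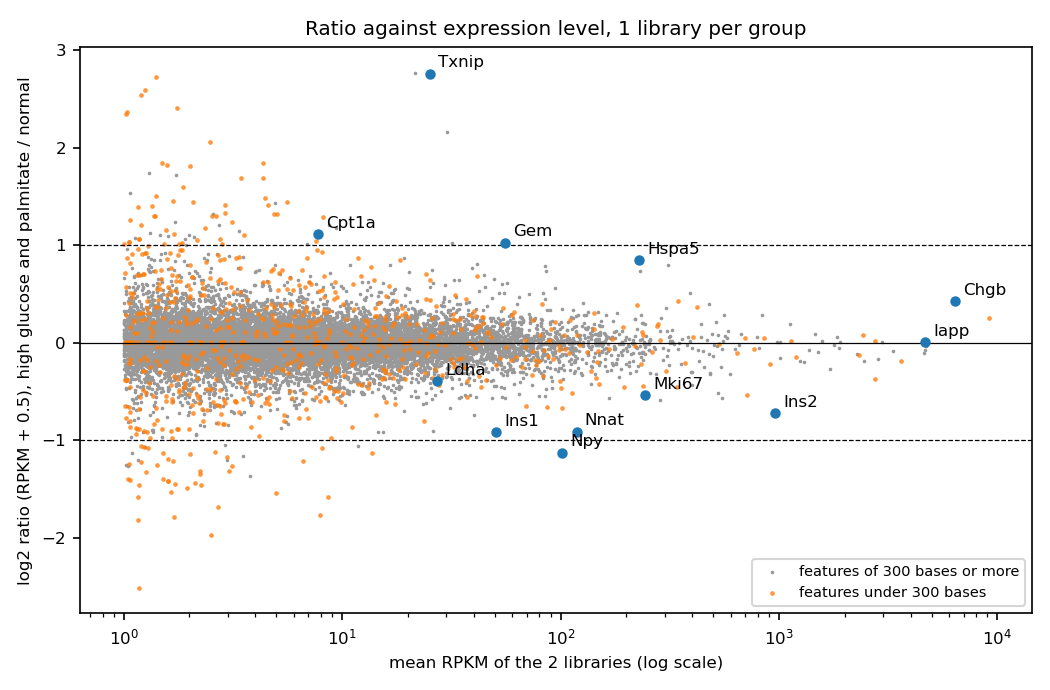
Each point is 1 of the 13947 features, by its mean RPKM in the 2 libraries (log axis) and its log2 ratio of treated to normal on the scale of RPKM plus 0.5, with dashed lines at 2-fold. Features under 300 bases (orange) hold most of the points past 2-fold at low levels, and Txnip lies highest among the labelled genes at 2.76.

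Genes with assigned symbols and a mean RPKM of at least 5 were ranked by log2 ratio on the scale of RPKM plus 0.5. Txnip, a glucose-induced inhibitor of thioredoxin, came first, going from 6.11 to 44.2 RPKM, a ratio of 7.23 (6.73 to 7.78). Next among those genes of at least 300 bases were Rgs16, a regulator of G protein signalling, at 2.38 (2.16 to 2.63), and Cpt1a, which controls fatty acid entry into mitochondria, at 2.29 (2.16 to 2.43). They were followed by the GTP-binding protein gene Gem at 2.05, Lbh at 2.14, the chemokine gene Ccl2 at 1.85 (1.69 to 2.04), the chaperone gene Hspa5 at 1.80 (1.77 to 1.83) and the acyl-CoA synthetase gene Acsl4 at 1.76. Beside Ins1, the lowest in that ranking with at least 300 bases were Npy, which encodes neuropeptide Y, at 0.457 (0.430 to 0.485), and Ifitm1 at 0.517. The imprinted gene Nnat stood at 0.531, Nrtn, the gene of the growth factor neurturin, at 0.522 and the receptor phosphatase gene Ptprz1 at 0.531. The same ranking also held short RNAs with few reads. Mir125a had 8 reads in the normal and 22 in the treated library, Mir22 had 20 and 43, Snora43 had 29 and 55, and Mir704 had 44 and 80. In the other direction the mitochondrial tRNA genes mt-Tv and mt-Tt had 38 and 39 reads in the normal library and 10 and 12 in the treated one. Mir7119 had 20 and 6, Mir7k 54 and 24, Mir5046 31 and 15, and Mir7648 34 and 18. Mir125a, Mir22, Snora43, Mir704, Mir5046 and Mir7648 overlap exons of longer genes on the same strand, such as Pdia4 for Mir704, so their reads cannot be told from those of the host genes. Exons of Txnip, Rgs16 and Nnat overlap predicted genes on the opposite strand, and whether counting used strand is not given in the sources used here, so reads of the pairs cannot be assigned to 1 strand.

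**Figure D3:**
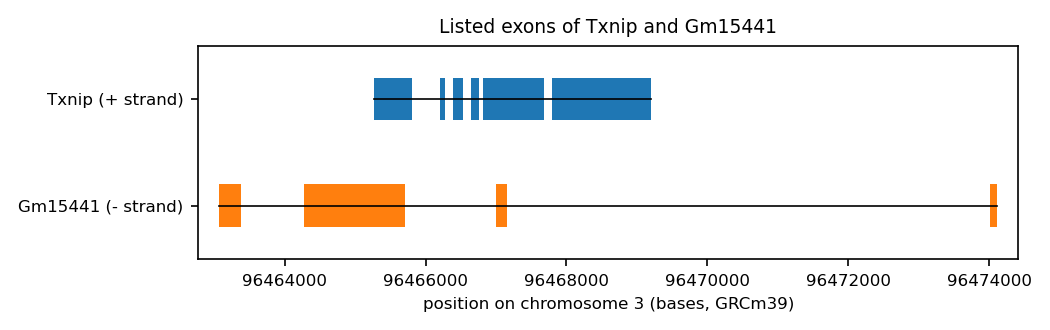
Exons listed for Txnip (plus strand) and the predicted gene Gm15441 (minus strand) along chromosome 3, in bases of GRCm39. The exons of the 2 genes share 606 bases, of 3123 exonic bases in Txnip and 2013 in Gm15441.

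Genes of glycolysis were lower in the treated library almost without exception. Of 19 measured members 17 had a log2 ratio below 0, and the median of -0.19 lay at the 0.01 percentile, although no member differed by 1.5-fold. After Ldha the lowest ratios were those of Pfkl, a phosphofructokinase gene, at 0.774, of Gpi1 at 0.780 and of Pgk1 at 0.795. The hypoxia list went further, with a median of -0.30 at the 0.00 percentile and 13 of 16 members below 0. Ankrd37, a target of hypoxia-inducible factors, was lowest at 0.607 (0.560 to 0.657), followed by the glucose transporter gene Slc2a1 at 0.699, the pyruvate dehydrogenase kinase gene Pdk1 at 0.706 and the prolyl hydroxylase gene P4ha2 at 0.745. Hif1a itself had a ratio of 1.17 and Vegfa one of 1.09. Exons of Ankrd37 and Slc2a1 overlap genes on the opposite strand, and the lists share Pgk1.

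Genes that handle lactate and pyruvate had a median of -0.08 at the 4.18 percentile, within the range of 95% of random lists, with 13 of 16 members below 0. The lowest was Pcx, the gene of pyruvate carboxylase, at 0.650 (0.604 to 0.700), and the mitochondrial pyruvate carrier gene Mpc2 stood at 0.715. The list of histone lactylation and acetylation enzymes, which also holds related genes, did not stand apart, with a median of 0.03 at the 82.45 percentile and 13 of 21 members above 0. The acetyltransferase genes Kat2b, Kat8 and Ep300 had ratios of 0.810, 1.12 and 1.11. Suclg2, which encodes a succinyl-CoA synthetase subunit, had one of 0.854, and Dpf2, which encodes a reader of histone marks, one of 1.15. Nuclear genes of oxidative phosphorylation had a median of -0.05 at the 10.71 percentile, with Cox5a at 0.777 and Cox6c at 0.792. All 9 measured mitochondrially encoded mRNAs were lower, with a median of -0.17 at the 1.44 percentile, and mt-Nd3 and mt-Nd2 had ratios of 0.803 and 0.829. The percentile was 6.35 with no filter on low values, and it was 4.51, with a median of -0.11 over 8 of the 9 members, when a trend in GC content and length was removed and features under 300 bases were left out. How much of that move comes from the trend was not tested. Both percentiles lie within the range of 95% of random lists. Another 4 mitochondrial mRNAs, mt-Co2, mt-Co3, mt-Atp6 and mt-Atp8, had at most 39 reads in either library. Gm28661, Gm10925 and Gm28437, nuclear copies identical to mt-Co2, mt-Atp6 and mt-Co3, had log2 ratios of -0.099, -0.072 and -0.057. The list's median and percentile leave these copies out, and their ratios are smaller in size than that median.

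Chaperones and other genes of the unfolded protein response were higher in the treated library. Of 24 measured members 23 had a log2 ratio above 0, and the median of 0.28 was above nearly all random lists (100.00 percentile). The 4 members at least 1.5-fold higher were Hspa5, which encodes the chaperone BiP, at 1.80, Selenos at 1.58 (1.48 to 1.68), Creld2 at 1.53 and Hyou1 at 1.52. The sensor genes Atf6, Ern1 and Eif2ak3 had smaller ratios of 1.22, 1.22 and 1.15, and Edem1 at 0.925 was the exception. Genes of the integrated stress response had a median of 0.17, also at the 100.00 percentile, with 21 of 23 members above 0. Its 2 members past 1.5-fold were the transcription factor gene Atf3 at 1.70 (1.60 to 1.80) and Ppp1r15a, which encodes a phosphatase subunit that restores translation, at 1.67. Atf4 stood at 1.17 and Chac1 at 1.32, whereas Ddit3, which encodes the death-related factor CHOP, stood at 0.857 (0.836 to 0.878). Exons of Ppp1r15a and Ddit3 overlap genes on the opposite strand. RNAs often read as a sign of RNA quality moved with these groups. The list of long and nuclear non-coding RNAs had a median of 0.29 at the 99.78 percentile, with all 5 measured members above 0, among them Neat1 at 1.23, Snhg1 at 1.40 and Rn7sk at 3.20 (1.64 to 6.72, from 12 and 38 reads). The percentile of that list was 94.21 with no filter on low values.

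The medians of the ChREBP and fatty acid oxidation lists were above nearly all random lists. Targets of the glucose-sensing factor ChREBP and genes of fatty acid synthesis had a median of 0.23 at the 100.00 percentile, with 17 of 19 members above 0. The 3 members past 1.5-fold were Txnip, its relative Arrdc4 at 3.10 (2.66 to 3.62) and the transcription factor gene Klf10 at 1.78 (1.67 to 1.91). The desaturase gene Scd2 stood at 1.42, the fatty acid synthase gene Fasn at 1.02 and Mlxipl, which encodes ChREBP, at 0.923. Genes of fatty acid oxidation and targets of PPAR had a median of 0.16 at the 99.94 percentile, with 12 of 19 members above 0 and 7 below. Only Cpt1a was past 1.5-fold on the scale of RPKM plus 0.5. On plain ratios the others included the carnitine carrier gene Slc25a20 at 1.49, the uncoupling protein gene Ucp2 at 1.53 and the lipid droplet gene Plin2 at 1.38, while Hadh at 0.784 and Ppard at 0.778 lay below 1. Genes of cholesterol synthesis had a median of -0.01 at the 43.90 percentile, with Mvk at 0.738 and Fdps at 1.21. The median of 0.29 of the long and nuclear non-coding RNAs went the same way as the ChREBP and fatty acid oxidation lists, and as those of dedifferentiation, other islet endocrine, and ductal and epithelial markers.

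Genes of the cell cycle were lower in the treated library, with 25 of 27 members below 0 and a median of -0.27 at the 0.00 percentile. The mitotic cyclin gene Ccnb2 had the lowest ratio at 0.643 (0.598 to 0.690) and was the only member past 1.5-fold on the log2 scale used. The mitotic kinase gene Plk1 stood at 0.665, the proliferation marker Mki67 at 0.689 (0.683 to 0.695) and Birc5 at 0.700. Among members of the replication helicase, ratios ran from 0.924 for Mcm3 and 0.935 for Mcm7 through 0.971 for Mcm5 and 0.977 for Mcm2 to 1.00 for Mcm6 and 1.03 for Mcm4. Exons of Plk1 overlap a predicted gene on the opposite strand.

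Inflammatory genes and NF-kB targets had a median of 0.21 at the 99.96 percentile, with 12 of 13 members above 0. On the scale of RPKM plus 0.5, the 3 members past 1.5-fold were Ccl2, the nitric oxide synthase gene Nos2 at 1.68 (1.60 to 1.76) and the receptor gene Tlr2 at 1.71 (1.41 to 2.09), while Tnf, with a plain ratio of 1.53 (1.16 to 2.01), was below it on that scale. Interferon response genes showed no shift as a group, with a median of 0.00 at the 47.55 percentile. Mx1 stood at 0.808, Usp18 at 0.841 and Rsad2 at 1.30. Immediate early genes had a median of 0.18 at the 99.82 percentile, with 11 of 13 members above 0, led by Nr4a2 at 1.85 (1.64 to 2.09), Fos at 1.53 and Egr1 at 1.36. The list of long and nuclear non-coding RNAs moved the same way as both groups, with the median of 0.29 given above.

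The remaining groups of cell function lay within the range of 95% of random lists. Oxidative stress genes had a median of 0.04 at the 89.95 percentile, with Slc7a11, a cystine transporter gene, at 1.35 and Hmox1 at 0.852. Apoptosis genes and p53 targets had a median of 0.07 at the 93.90 percentile, with Phlda3 at 1.61, Bid at 1.60 and Cdkn1a at 1.37. Genes of insulin granule exocytosis had a median of 0.01 at the 72.20 percentile, and within it the granule docking gene Sytl4 stood at 0.695 (0.679 to 0.711) and Vgf at 1.44. Genes of TGF-beta signalling and extracellular matrix had a median of 0.09 at the 92.88 percentile, with the laminin gene Lamc1 at 1.44 (1.30 to 1.60). Autophagy and lysosome genes had a median of 0.02 at the 72.93 percentile, with the lysosomal channel gene Mcoln1 at 0.678. Cytosolic heat shock genes had a median of 0.02 at the 73.89 percentile, with Hspa1a at 0.646, and ribosomal protein genes one of 0.03 at the 95.35 percentile.

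**Figure D4:**
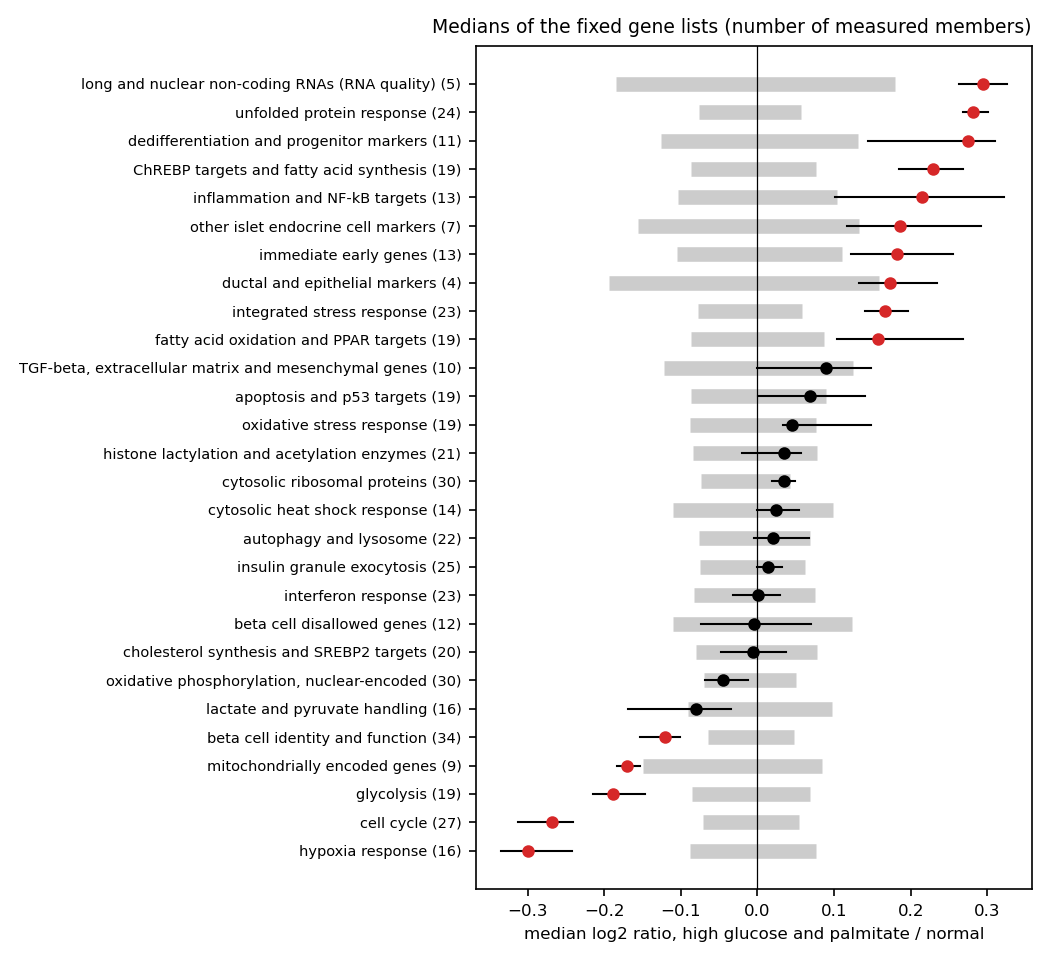
Each point is the median log2 ratio of treated to normal over the measured members of a gene list, for the 28 lists with at least 4 of them. Black lines are 95% counting intervals, grey bars hold the middle 95% of the 10000 random lists, and red marks the 15 medians in either outer 2.5% of those lists.

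Markers of other pancreatic cell types were sparse. None of the 8 fibroblast markers in the table reached a mean RPKM of 1, and of acinar markers 2 did, with a median log2 ratio of 0.47, among them the transcription factor gene Bhlha15 at a ratio of 2.81 (2.18 to 3.65). The 3 endothelial and leukocyte markers measured had a median of 0.28 and went both ways, with Cd68 at 2.24, Plvap at 1.31 and C1qa at 0.539. The 4 ductal and epithelial markers measured were all higher, with a median of 0.17 at the 98.18 percentile. Among them the secreted phosphoprotein gene Spp1 had 225.7 RPKM in the normal and 393.5 in the treated library, a ratio of 1.74, and shares exons with a predicted gene on the same strand. The features with the highest RPKM in either library were the chromogranin genes Chgb and Chga, Iapp, and the predicted genes Gm54730, Gm28661 and Gm10925. Gm54730 stood at 8332 and 9907 RPKM, overlaps exons of the chaperone gene Hsp90b1 on the same strand and has 133 bases, so its reads cannot be told from those of Hsp90b1.

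Of the 28 lists with enough members, 15 had medians in the outer 2.5% on either side of the random lists, 10 above and 5 below. By chance 1.4 would be expected if lists were independent and genes within a list did not vary together. The lists share genes, and with 1 library per group the percentiles cannot tell a difference between treatments from one between 2 cultures.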

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

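The alternatives restricted to features of at least 300 bases and to features with no opposite-strand exon overlap were chosen after seeing the data. The number of features at least 2-fold apart varied with the settings, from 75 higher and 51 lower. A pseudocount of 0.1 gave 105 higher and 82 lower, a pseudocount of 1 gave 46 and 33, and rescaling to the same total gave 102 and 79, for which the cause was not tested. A mean RPKM of at least 5 left 13 higher and 8 lower, and no filter gave 201 and 146. A 1.5-fold threshold gave 243 and 207. Requiring an interval that excludes 1 left 54 higher and 29 lower, requiring an assigned symbol left 40 and 29, and a length of at least 300 bases left 25 and 11, which are smaller subsets by construction. Other scalings moved the median log2 ratio of all features by 0.0233 or less in size. None of the 1005 values of 201 named genes changed direction, and 24 moved beyond their counting interval. Of 269 list medians 27 moved beyond theirs. Changes of direction were looked for only in the 15 lists in the outer 2.5%, and none was found there. Dedifferentiation markers, mitochondrially encoded genes and long non-coding RNAs left the outer 2.5% with no filter on low values. The other 12 lists stayed there in every setting in which they were scored. Without features that overlap opposite-strand exons, too few ductal and epithelial markers and long non-coding RNAs remained to score. Depth limits features under 300 bases most, while the difference between 2 single cultures limits every result and was not measured.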

Other observations

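The tests of library scaling and those of opposite-strand gene pairs were chosen only after the results were seen. Genes of cell division outside the fixed list followed it. Of 45 genes of G2 and M phase, 44 were lower in the treated library, with a median log2 ratio of -0.38 at the 0.00 percentile of matched random lists. They included the kinase gene Nek2 at a ratio of 0.676, the kinesin gene Kif2c at 0.684 and the centromere gene Cenpe at 0.681, with Cks1b at 1.22 as the exception. Of 34 S phase genes 29 were lower, with a smaller median of -0.17, also at the 0.00 percentile. Whether the 2 medians differ was not tested.

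Some further genes of at least 300 bases are named here after their values were seen, and they form no tested group. Inhba, which encodes a subunit of activin, had a ratio of 3.03 (2.78 to 3.31), Fkbp11, an endoplasmic reticulum foldase gene, one of 6.82 (4.88 to 9.75) and Stmn4 one of 5.40 (3.93 to 7.57). Angiotensinogen (Agt) at 1.67 and prodynorphin (Pdyn) at 1.63 were higher at levels of 173.2 and 34.1 RPKM in the normal library, as was the fructose bisphosphatase gene Fbp2 at 1.73. Lower were the synaptic vesicle gene Sv2b at 0.422 (0.384 to 0.463), Lyve1 at 0.393 and the interferon-induced gene Gbp2b at 0.336. The insulin genes, with 1197 and 66.0 RPKM in the normal library, stood well below Chgb at 5472, Chga at 4740 and Iapp at 4664 RPKM.

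The glycolysis and hypoxia lists were both lower in a library from cells labelled with high glucose, while ChREBP targets were higher. Scaling set by a few abundant genes is argued against, because over 3 other scalings the higher of the 2 medians was still -0.165. A trend in GC content and gene length is argued against as well, because after its removal, over all 19 glycolysis and 15 of 16 hypoxia members, the higher of the 2 percentiles was 0.00, and the trend held 0.518% of the variance. A candidate explanation is lower activity of hypoxia-inducible factors in the treated culture. Targets outside both lists lay at the 0.01 percentile, with 18 of 25 lower, among them Ak4 at 0.660 and Fam162a at 0.684, while Hif1a mRNA was not lower, and cell density or medium of the single cultures stays open.

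Genes whose exons overlap on opposite strands shared their ratios, Txnip at 7.23 and its antisense neighbour Gm15441 at 7.37 among them. Across 2259 such pairs Pearson's r of the log2 ratios was 0.474 and Spearman's rho 0.424, and r was 0.430 without the Txnip pair. Pairs are not independent replicates. General co-regulation of neighbours is argued against, because 1472 opposite-strand pairs within 5 kb that do not overlap gave an r of 0.0837. Counting without regard to strand may therefore account for part of the shared ratios, though regulation by antisense transcripts stays open, since 1 value per gene cannot separate them.

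The 3 mRNAs mt-Co2, mt-Atp6 and mt-Co3 of the mitochondrial genome were nearly empty, while predicted genes on chromosome 1 at 24652270 to 24654646 (GRCm39) ranked among the most abundant features. In the normal library mt-Co2 had 0 reads, mt-Atp6 had 1 and mt-Co3 had 29, against 142875 for Gm28661, 142150 for Gm10925 and 66141 for Gm28437. Over their whole lengths of 681, 678 and 783 bases the predicted genes were 100% identical to these mRNAs in GRCm38, so reads shared with nuclear copies of mitochondrial DNA are a likely source of the signal. By contrast mt-Co1 kept 123242 reads beside Gm29216, its 98.78% identical partial copy. How the counting chose between copies is not given in the sources used here, and the share of reads from mitochondrial genes (2.09% and 1.91%) leaves out these copies, with 0.847% and 0.804%.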
